A study of Arabidopsis thaliana with 8 samples.

How the data were processed

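The series holds 8 arrays of Arabidopsis thaliana, 4 of leaf and 4 of root RNA, and groups and replicate numbers were taken from the sample titles. The deposited values are spot intensities, 1 per probe and array, with 3439 probes per array. The steps the authors took to make the intensity values, from hybridisation to background correction and scaling, are not given in the sources used here. From the values themselves, the intensities were linear and relative, with between 2 and 6 probes per array at the same ceiling just below 100 and between 12.8% and 22.8% of probes at exactly 0. The number of arrays limits the precision, and intensities at 0 carry no information on how far below detection a transcript lay. Every value column belonged to a sample.

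Gene names came from the platform's annotation, joined by probe number. Of the 692 probes with 1 gene, 690 matched a locus of the RefSeq gene table for assembly TAIR10.1, which was used for names only. No genome build is named for the values, so no coordinates are printed. Of the 3439 probes, 870 were annotated to several genes, mostly similar copies, and their signal cannot be assigned to 1 of them. Among 85 pairs of probes with the same such annotation, the log2 differences correlated at r = 0.174 across pairs (permutation test, two-sided, p = 0.111) and the levels at -0.019 (p = 0.868), with the same sign of difference in 57.6%, so a value of such a probe may not stand for each gene it names.

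The rules for scale, normalisation, floor, test, threshold, gene lists and named genes were fixed before the data were examined. As the array medians and means differed by more than 5%, the intensities were quantile normalised between arrays, floored at the 1st percentile of the positive values (0.00582) and taken to log2. The 141 probes at the floor on all arrays were left out, which left 3298. Root was compared with leaf by limma 3.58.1 in R 4.3.3, with lmFit and eBayes, tissue as the only term, a two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences are root minus leaf on the log2 scale with limma's moderated standard error, and intensities are means ± SD of the deposited values. Figures were drawn with matplotlib 3.10.9.

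Named genes followed a rule: the 12 probes with the largest difference towards each tissue, among those past the threshold, without overlap between the tissues, and above the median probe of the higher tissue; the largest members of any list whose set test passed, which gave none; and a short set of sentinel genes, of which only RCA was measured, on probes it shares. Because this ranking returned few probes with a gene name, the same ranking among probes with exactly 1 gene was added after the data were seen. List members are named where they passed the threshold, with some of those that did not. NdhS and the genes described under the other observations were chosen after their values were seen.

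The 27 gene lists, chiefly plastid functions with tissue and state markers, held 471 genes after 4 were left out because the locus did not carry the intended name. Only 46 of them had a probe, on 17 lists. A list was tested when 3 or more of its probes were, which 5 lists and the union of 4 photosynthesis lists (leaf mesophyll markers, which contains the Calvin cycle list) met. The tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 6 lists. Summaries of arrays were compared by exact permutation tests.

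Alternatives fixed beforehand were the deposited intensities without normalisation, centring on array medians, scaling to a common mean, a floor at the 5th percentile, values of 0 set to missing, an offset at the 10th percentile, leaving out the dimmest 25% of probes, a replicate block, other variance models, a separate-variance test of each probe, leaving out each array in turn, other set tests and list members on single-gene probes only. Added after the data were seen were a block for replicates 1 and 2 against 3 and 4, averages within these subsets, each subset alone, leaving out probes with numbers divisible by 6, and scaling on all but the brightest 5% of probes. Calls were also counted over all 35 splits of the arrays into 4 and 4.

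The test was tried on simulated data with the 3298 probes and arrays of this comparison. It recovered 0% of the probes changed by 0.5 on the log2 scale, 60% at 1, 82% at 2 and 100% at 4, with 7 false calls among 128. The changed probes were drawn from those above the median level. In simulated lists of 9 probes shifted by -2, camera called 100 of 100 at an unadjusted p below 0.05, and 8 of 100 without a shift. In both simulations noise was independent between probes, and probes not chosen to change had no tissue difference. In the data 42.2% of the probes were called, so these rates do not carry over to the list tests.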

Results

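Gene expression was compared between leaves and roots of wild-type Arabidopsis thaliana plants of the Columbia 0 ecotype. The labels assign 4 arrays to leaf and 4 to root, each carrying total RNA from 1 tissue. Each array gave a spot intensity for 3439 probes, on a relative scale that ran from 0 to a ceiling just below 100. The summed intensity of an array lay between 3021 and 3426 in leaf and between 2868 and 3505 in root. On average 21.4% ± 1.59 of the leaf probes and 13.9% ± 1.23 of the root probes were listed at exactly 0 (SD, n = 4 arrays per tissue; two-sided exact permutation test over 70 relabelings, p = 0.0286, the smallest it can give). A single gene was annotated to 692 probes, several genes were annotated to 870, and 1877 probes carried no gene name in the sources used here.

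The labels give 1 purpose for the series, the contrast of root with leaf tissue. Of 8 tested probes for photosystem, antenna and Calvin cycle genes, 5 were lower in root and 1 was higher. The probe for LHB1B2 (AT2G34420), a chlorophyll a/b-binding protein of the light-harvesting antenna, read 22.5 ± 2.53 in leaf and 0.481 ± 0.174 in root (SD, n = 4 arrays each), a log2 difference, root minus leaf, of -5.60 ± 0.24 (SE). PRK (AT1G32060), the Calvin cycle enzyme that makes the acceptor of carbon dioxide, read 3.48 ± 0.935 in leaf and 0.141 ± 0.0468 in root, a difference of -5.15 ± 0.37. In the other direction, the plastid ribosomal protein gene AT5G65220 read 3.20 ± 1.65 in leaf and 40.8 ± 21.2 in root, a difference of 3.66 ± 0.39. Its spread lay mainly between replicates 1 and 2 and replicates 3 and 4. Root read 60.7 and 57.5 against 22.1 and 22.9, and leaf 4.59 and 4.66 against 1.82 and 1.71. The photosystem II subunit gene PSBW (AT2G30570) was also brighter in root, at 70.8 ± 8.33 against 25.1 ± 1.24 in leaf.

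Of the 3298 probes tested, limma called 664 higher in root and 729 higher in leaf at a Benjamini-Hochberg adjusted p below 0.05, which together were 42.2% of the probes. Of these, 596 were at least 2-fold higher in root and 651 at least 2-fold higher in leaf. Called probes included 72 that were listed at 0 on all 4 leaf arrays and 29 that were listed at 0 on all 4 root arrays, for which no fold is given. After normalisation and flooring, the log2 values of the tissues did not overlap at 1457 probes, or 44.2%. Chance gives 2.86% if the arrays are independent, which the labels do not state. The count includes probe 1431, which was at the intensity ceiling on every array and was separated by the normalisation alone (6.624 in leaf and 6.644 in root). The balance of the calls depended on the scaling between arrays: on the intensities as deposited, 1137 probes were called higher in root and 495 higher in leaf, so that root took 69.7% of the calls instead of 47.7%, and the median log2 difference of all probes moved from 0.05 to 0.80. When replicates 1 and 2 of each tissue were averaged, and likewise replicates 3 and 4, the counts fell to 336 and 370.

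**Figure D1:**
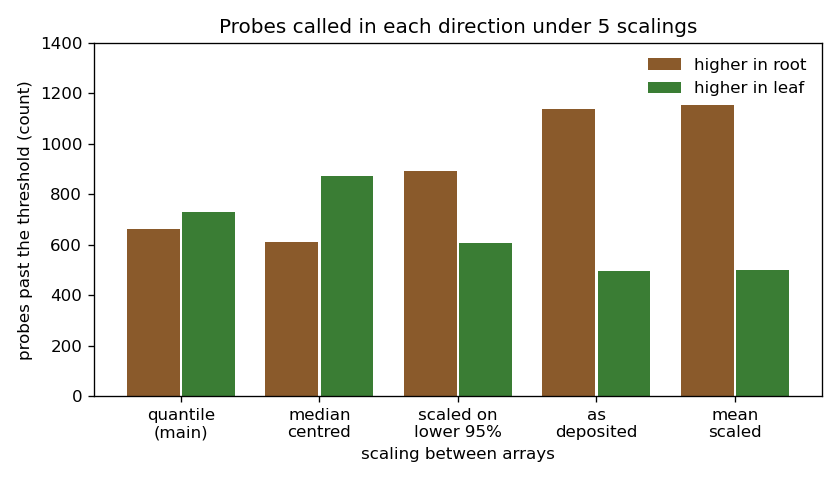
Number of probes past the adjusted p threshold in limma (vertical axis, count) that were higher in root (brown bars) or higher in leaf (green bars), under 5 ways of scaling the 8 arrays (horizontal axis). Quantile normalisation gave 664 and 729 probes, and the deposited intensities gave 1137 and 495.

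Among the gene lists fixed beforehand, the leaf mesophyll markers combined photosystem I and II subunits, light-harvesting proteins and Calvin cycle enzymes, and 8 of their probes could be tested. Of these 8, 5 fell in root, 1 rose and 2 did not pass the test, both over all probes and adjusted over the list alone, with a median log2 difference of -2.85. PSAN (AT5G64040), a photosystem I subunit, read 4.14 ± 0.688 in leaf and 0.309 ± 0.0594 in root (log2 difference -3.998 ± 0.182 after normalisation and -3.75 as deposited; limma, adjusted p = 4.09e-06), with leaf replicate 3 below the other leaf arrays. PSBY (AT1G67740), a photosystem II subunit, fell by 1.70 on the log2 scale (limma, adjusted p = 5.11e-04). A probe shared by LHCB4.1, LHCB4.2 and LHCB4.3, the genes of a minor antenna protein, fell by 5.52 (limma, adjusted p = 3.14e-04), a size that the floor sets in part, since 1 root array was listed at 0 (-4.50 with the 5th percentile floor and -3.39 with the offset). PSBW was the member that rose, by 1.72 ± 0.26 (0.66 with median centring; limma, adjusted p = 1.37e-03). Both probes that did not pass are shared by RCA, the gene of Rubisco activase, and AT1G73110, with differences of 0.16 ± 0.29 and 0.11 ± 0.89; the dimmer of these lay on an array position at which most probes were listed at 0. As a set the list did not pass camera against the other probes (p = 0.0109, adjusted p = 0.0653 over 6 lists; adjusted p = 0.233 with an estimated correlation). It passed without root replicate 1 (camera, adjusted p = 0.0357) and on the deposited intensities (0.0193), within a range of 0.0141 to 0.477 over 23 alternatives. SBPASE, another Calvin cycle gene, was at the floor on all arrays and was not tested.

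**Figure D2:**
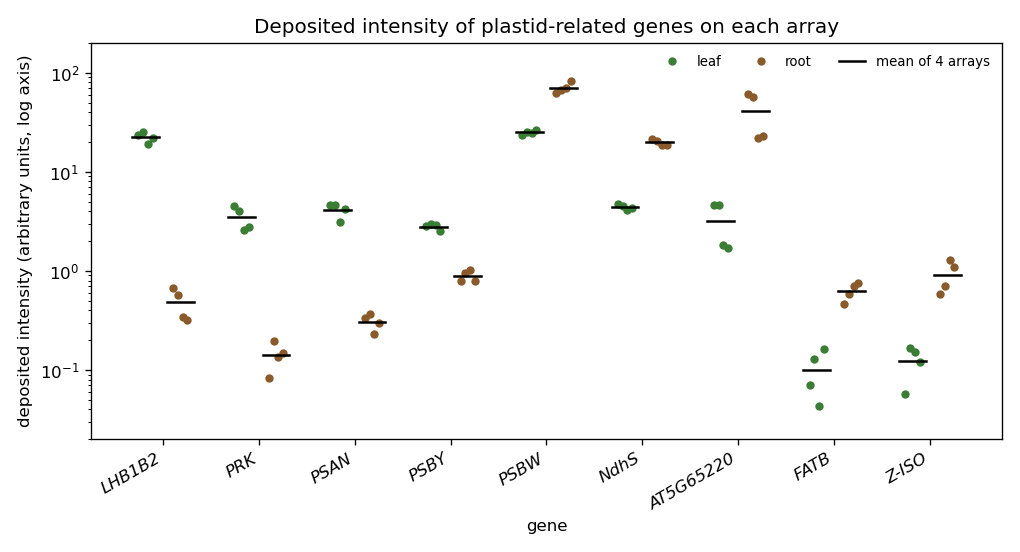
Deposited intensity (vertical axis, arbitrary units, log scale) of 9 genes on each of the 4 leaf arrays (green points) and 4 root arrays (brown points), with a black line at each mean. LHB1B2, PRK, PSAN and PSBY lie higher in leaf, and PSBW, NdhS, AT5G65220, FATB and Z-ISO lie higher in root, under each of the 5 scalings tried.

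Of 5 probes for genes of plastid fatty acid and galactolipid synthesis, 4 rose in root and 1 did not pass. These counts held both over all probes and adjusted over the list alone. The median log2 difference was 0.96, and with median centring 3 rose and 1 fell. The probe that did not pass was a further probe for AT5G10160 and AT2G22230, at -0.81 ± 0.74. It was listed at 0 on 3 leaf and 4 root arrays. A probe shared by FATB, FaTA and AT4G13050 was at the floor on all arrays and was not tested. FATB (AT1G08510), a thioesterase that releases fatty acids from their carrier protein, read 0.101 ± 0.0546 in leaf and 0.625 ± 0.130 in root (SD, n = 4; log2 difference 1.92 ± 0.41; limma, adjusted p = 6.75e-03). AT1G24360, an enzyme of the fatty acid elongation cycle, differed by 0.96 ± 0.22 (1.52 as deposited, 0.69 with median centring; limma, adjusted p = 0.0107). The other probes that rose were shared between genes, and neither passed the separate-variance test (adjusted p = 0.120 and 0.0768). The probe of FaTA and AT4G13050 lost its call without any 1 of the root replicates or leaf replicate 2 or 3, with adjusted p from limma between 0.0544 and 0.0742 (0.00350 to 0.274 over 25 alternatives). The probe of AT5G10160 and AT2G22230 that rose did so without root replicate 1, 2 or 3 or leaf replicate 1, 3 or 4. Its adjusted p from limma was then between 0.0541 and 0.106 (0.0129 to 0.453 over 25 alternatives). The list did not pass camera (p = 0.0862, adjusted p = 0.259; adjusted p = 0.392 with an estimated correlation).

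Plastid ribosomal protein genes moved in both directions. Of 6 probes, 1 rose (AT5G65220; limma, adjusted p = 2.30e-04), 1 fell and 4 did not pass the test, both over all probes and adjusted over the list alone. The member that fell, AT3G54210, differed by -1.29 ± 0.35 (-0.81 as deposited; limma, adjusted p = 0.0207) and lost its call without root replicate 1 (adjusted p = 0.0563; 0.00220 to 0.157 over 25 alternatives). Without leaf replicate 3, AT3G13120 and AT4G01310 were called higher in root (limma, adjusted p = 0.0257 and 0.0461), with 0.00489 to 0.967 and 0.0129 to 0.263 over their alternatives. Both were also called on the deposited intensities, where 3 of the 6 probes rose and 1 fell. Camera gave an adjusted p of 0.629, and 0.646 with an estimated correlation.

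For plastid thioredoxins and antioxidant enzymes, 2 of 7 probes rose and 5 did not pass, over all probes and adjusted over the list alone. On the deposited intensities 4 of the 7 rose, NTRC and the probe shared by GR and GR1 having been added (limma, adjusted p = 0.0279 and 0.0354), and with median centring 1 rose and 1 fell. AT3G52960, a plastid peroxiredoxin, was listed at 0 on 3 leaf arrays and read 0.220 ± 0.0504 in root (limma, adjusted p = 0.0111; separate-variance test, 0.0640). The probe shared by TAPX and SAPX, ascorbate peroxidase genes, rose by 0.95 ± 0.27 (1.52 as deposited, 0.69 with median centring; limma, adjusted p = 0.0256), and it lost its call without root replicate 1 or 2 or leaf replicate 3 or 4, with adjusted p of up to 0.0628 (0.00202 to 0.191 over 25 alternatives). A further probe for the same genes read 0.0418 in leaf and 0.0361 in root, with 1 array of each at 0, so that its difference of -1.66 ± 1.14 depended on normalisation and floor (-0.194 as deposited, -0.694 with the offset). It passed only without leaf replicate 3 among the arrays left out (adjusted p = 0.0482; 0.00937 to 0.956 over 24 alternatives). AT2G04700, at -2.42 ± 0.90 but -1.07 as deposited and -1.37 with the offset, passed without root replicate 2 or 3 (adjusted p = 0.0266 and 0.0331; 0.0132 to 0.217 over 25 alternatives). Camera gave an adjusted p of 0.629, and 0.646 with an estimated correlation.

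Tetrapyrrole and chlorophyll synthesis had 4 probes, of which 1 rose and 3 did not pass, over all probes and adjusted over the list alone (camera adjusted p = 0.659; 0.711 with an estimated correlation). The probe that rose, AT1G74470, which encodes geranylgeranyl reductase, differed by 0.75 ± 0.16 (limma, adjusted p = 6.30e-03), but by -0.38 when the arrays were centred on their medians, and on the deposited intensities 0 of the 4 probes passed. CHLM, a methyltransferase of the chlorophyll branch, stood at -0.36 ± 0.26 and did not pass. Of 3 Calvin cycle probes, PRK fell (limma, adjusted p = 3.44e-05) and both RCA probes did not pass. The median of this list was 0.11 and its mean -1.63, and camera gave an adjusted p of 0.629, or 0.646 with an estimated correlation.

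Lists with fewer than 3 measured probes were not tested as sets. Z-ISO (AT1G10830), an isomerase of carotenoid synthesis, was higher in root, at 0.917 ± 0.330 against 0.124 ± 0.0489 in leaf (SD, n = 4; log2 difference 2.203 ± 0.451 after normalisation and 2.92 as deposited; limma, adjusted p = 5.78e-03). APS4 (AT5G43780), an ATP sulfurylase of sulphur assimilation, rose by 1.72 ± 0.42 (2.46 as deposited; limma, adjusted p = 0.0137), but did not pass the separate-variance test (adjusted p = 0.0738). AT3G23940, dihydroxyacid dehydratase of branched-chain amino acid synthesis, fell by 2.69 on the log2 scale (limma, adjusted p = 3.98e-04), and AT3G58610 of the same list, at -0.37 ± 0.20, did not pass. The starch list held a probe shared by PWD and AT5G01260, which fell by 5.74 (limma, adjusted p = 3.11e-03); with 2 root arrays listed at 0, its size depended on the floor (-4.53 with the 5th percentile floor, -3.67 with the offset). It also held a probe shared by APL3 and APL4, at -0.55 ± 0.33, which did not pass. A probe shared by ATPC1 and ATPC2, genes of the ATP synthase gamma subunit, fell by 1.11 (1.69 with median centring; limma, adjusted p = 1.11e-03). The only measured members of the lists for photorespiration (LrgB, -1.19 ± 1.07, on a position where most probes were listed at 0), plastid protein import (a probe shared by SPP and AT5G56730, 0.46 ± 0.35), heterotrophic carbon supply (AT5G17630, 0.21 ± 1.11) and aromatic amino acids (a probe shared by AT2G45300 and AT1G48860, 0.62 ± 0.49) did not pass. No probe matched the lists of root markers, housekeeping genes, stress or senescence markers, seed and vascular markers, or 6 further plastid and mitochondrial lists.

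With the floor used, the largest differences towards root belonged to genes listed at or near 0 in leaf. AT4G15790 was listed at 0 on all 4 leaf arrays and read 5.46 ± 4.11 in root (SD, n = 4). AT2G26110 and AT4G02580, a subunit of mitochondrial complex I, were likewise listed at 0 on all leaf arrays and read 0.930 ± 0.275 and 0.919 ± 0.454 in root. These 3 genes were among the 12 probes ranked highest towards root, of which 2 more were shared between genes, 7 carried no gene name, and 9 were listed at 0 on every leaf array. With the ranking restricted to probes with 1 gene, the others were AT1G11730, AT2G37750, AT4G22190, AT5G59400, AT4G17440, AT4G20690, AT4G12270, AT1G05340 and AT2G47360, with root means between 0.369 and 1.67 and at most 0.0595 in leaf. All 12 passed limma, with adjusted p between 3.67e-07 and 0.0123. Both the order and the membership rest on the floor: ranked again, in an alternative chosen after the data were seen, 8 of the 12 stayed with the 5th percentile floor and 6 with the offset.

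Towards leaf, the 12 highest ranked probes included only 1 with a single gene, AT2G27680, an oxidoreductase gene that read 1.70 ± 0.880 in leaf and was listed at 0 on 3 of 4 root arrays (limma, adjusted p = 0.0156). Its difference of -6.26 became -4.44 with the 5th percentile floor and -3.78 with the offset, smaller in size than those of AT5G38360, LHB1B2 and PRK. Among probes with 1 gene, the others were AT5G38360, at 29.8 ± 2.21 in leaf and 0.610 ± 0.124 in root (log2 difference -5.75 ± 0.21; limma, adjusted p = 1.40e-06), LHB1B2 (limma, adjusted p = 2.78e-06), PRK, AT3G06570 and PSAN. Also in this set were AT1G53260, AT5G19210, THIC, AT3G47650, PRA1.B6 and AT1G32730, with log2 differences of at least 2.95 in size after normalisation and flooring. As deposited, their differences were smaller, between -2.41 (THIC) and -2.99 (AT3G47650). For AT1G53260, listed at 0 on 2 root arrays, the difference was -3.77, but -2.56 with the 5th percentile floor and -1.90 with the offset, so its place rests on the floor. THIC (AT2G29630), a plastid enzyme of thiamine synthesis, read 0.361 ± 0.0975 in leaf and 0.0881 ± 0.0512 in root, and AT3G47650, the gene of the Rubisco assembly factor BSD2, read 2.78 ± 0.254 and 0.353 ± 0.0608. The 24 single-gene probes ranked towards either tissue passed the threshold with any 1 array left out, with adjusted p from limma of up to 0.0459. When replicates were averaged within subsets, 21 of the 24 passed, the exceptions being AT2G27680, THIC and AT1G53260 (adjusted p = 0.0506, 0.0582 and 0.112). With the separate-variance test 19 passed, AT2G27680, AT4G22190, AT2G47360, AT1G53260 and THIC being lost (adjusted p of up to 0.0848). Of the 24, 23 passed under each of the 4 other scalings, AT1G53260 being the exception.

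At 5 probes a whole tissue sat at the intensity ceiling, so that its level is a lower limit. Probe 3499, with no gene name, was at the ceiling on all leaf arrays and read 4.43 ± 1.99 in root (SD, n = 4; at least 22.6-fold higher in leaf in deposited intensity; limma, adjusted p = 1.11e-05). Probe 1803, shared by AT5G51520 and AT4G25250, was at least 8.71-fold higher in leaf (limma, adjusted p = 5.31e-05), and probe 1159, with no gene name, at least 10.6-fold higher in root (limma, adjusted p = 1.59e-05). Probe 4360, shared by AT4G22850 and AT4G12000, was at the ceiling in leaf and read 85.1 ± 3.15 in root, and did not pass (limma, adjusted p = 0.498). As its leaf level is a lower limit, this does not show equal levels. Probe 1431, shared by CSLC12, AT4G07950 and AT4G07940, was at the ceiling on all 8 arrays.

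Arrays of the same tissue correlated at r = 0.751 to 0.968 across probes, and arrays of different tissues at 0.567 to 0.652; probes are not independent replicates, so these values describe the arrays only. The first principal component held 51.9% of the variance and separated the tissues, and the second, with 13.7%, separated replicates 1 and 2 from replicates 3 and 4 in both tissues. Within replicates 1 and 2 alone, 569 probes were called higher in root and 650 in leaf, and within replicates 3 and 4, 616 and 705. Over all 3298 probes the differences within the subsets correlated at r = 0.703, across probes. Averaging within the subsets ended the calls of 15 of the probes named above, PSBW, FATB, Z-ISO, APS4, AT1G24360, AT1G74470, AT3G52960 and AT3G54210 among them, with adjusted p from limma between 0.0506 and 0.191. The labels do not say whether replicates were separate plants or repeated measurements of the same RNA, so the p-values may rest on technical spread.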

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

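For PSBW and NdhS the tests of scaling, of probe names and of replicate subsets, alone or averaged, and for the balance of calls the scaling on the lower 95% of probes, were chosen only after the result was seen. Each group of 4 arrays was searched for an array far from the others, for the probes named in the text with values that allowed it, and 4 of 95 groups stood out, where chance gives about 1 in 20. All 4 were leaf groups, on the normalised log2 scale.

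LHB1B2 read 4.275 on leaf replicate 4 against 4.162 to 4.18 on the others. In deposited intensity, at 21.8, this array lay within the range of the others, 19.3 to 25.1, so it stood out only after normalisation. AT3G06570 read 2.191 on leaf replicate 2 against 2.184 on the others. PSAN read 1.676 on leaf replicate 3 against 1.985 to 2.034, or 3.15 against 4.19 to 4.62 in deposited intensity. Probe 4219, shared by 3 plastid thioredoxin genes, read -4.714 on leaf replicate 4 against -1.541 to -1.135, or 0.00401 against 0.269 to 0.376 in deposited intensity.

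PSBW and NdhS, which encode subunits of photosystem II and of the chloroplast NDH complex, read higher in root, unlike most photosynthesis genes measured. The scaling between arrays is argued against: over the 4 scalings fixed beforehand, the smallest difference of either probe was 0.659, for PSBW after median centring, with an adjusted p from limma of 0.0379. Whether a single subset of arrays was the source cannot be decided here, because both probes were singled out after their difference over all arrays was seen. The difference was present in each subset. Within replicates 1 and 2 it was 1.51 for PSBW and 2.513 for NdhS. Within replicates 3 and 4 it was 2.026 and 2.615 (SE over all arrays 0.26 and 0.15). The shared sign does not decide the question either, because 100% of the 1393 called probes kept their sign. Light from neighbouring spots stays open, because the positions of the spots are not known here and only numbers were compared (at most 5% of the probe's own root level 1, 6 or 12 numbers away), as does a wrong or shared probe name, with 0 further probes annotated to either gene. A higher transcript level of these genes in root is the biological alternative, untested. Averaging within the subsets of arrays left PSBW at an adjusted p of 0.0678 in limma, the highest of 25 alternatives, and NdhS at 0.0263. NdhN, a further NDH subunit gene also chosen after its values were seen, stood at -2.22 ± 1.16 and did not pass (limma, adjusted p = 0.164). It was listed at 0 on 2 leaf and 3 root arrays, so it cannot show whether other NDH subunit genes moved with NdhS. Its probe number, 2514, is also divisible by 6, a kind of position described under the other observations.

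The balance of calls between root and leaf moved with the scaling. The brightest 5% of probes held 62.9% ± 0.923 of the signal of a leaf array and 53.3% ± 0.560 of a root array (SD, n = 4 each). A two-sided exact permutation test gave p = 0.0286, the smallest it can give. Scaling on the other 95% reduced the median log2 difference from 0.803 to 0.506. With array means alike (0.939 in leaf and 0.929 in root), this drop largely follows from those shares and is no separate test. Whether a few bright probes account for part of the shift stays open. The larger number of leaf values listed at 0 is argued against as the whole of the shift. The median as deposited was still 0.437 among the 2087 probes above 0 on all 8 arrays. As this lies below 0.803, a part played by the values at 0 stays open. Whether root holds more of the transcripts measured, a biological difference, stays open and untested.

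Root and leaf differed at 1393 probes. Of the 35 splits of the 8 arrays, 1 gave as many, the real one, and the highest of the others gave 3. Every other split mixes the tissues, so their difference adds to its spread, and 3 is not a level of false calls. That the real split came first argues against chance as the source of the count if the 8 arrays are independent. With 35 splits chance cannot be excluded. The labels do not state that independence, and averaging within the subsets left 706 probes.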

How the results depend on the processing

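The alternatives on subsets of replicates, on numbers divisible by 6 and on the lower 95% of probes were chosen after the data were seen. As deposited, 1137 probes were higher in root (1055 at least 2-fold), 408 were at least 2-fold higher in leaf, and the median log2 difference was 0.803; with a common mean these values were 1155, 1060, 400 and 0.823. The median was 0.506 with scaling on the lower 95% of probes, -0.0877 with the 5th percentile floor and -0.221 with values of 0 missing. With replicates 1 and 2, and 3 and 4, averaged, 336 probes were higher in root and 370 in leaf, all at least 2-fold; fewer samples enter this fit. The cause of the other moves was not tested, apart from the scaling tests given above. Leaving out each array in turn gave 548 to 646 probes higher in root and 660 to 677 in leaf, 510 to 585 and 577 to 608 at least 2-fold, medians of 0.00718 to 0.0763, and 0 to 1 gene lists. No list passed camera in the main test, and 0 passed with an estimated correlation (adjusted p = 0.233 for the leaf mesophyll markers). That list alone passed as deposited, with a common mean, with the 5th percentile floor and with the offset. It also passed without root replicate 1, without numbers divisible by 6 and on the lower 95%. The same list passed with single-gene probes only (1 of 3 lists). With fry, which does not compare a list with other genes, 3 passed. AT1G74470 turned to -0.377 after median centring (limma, adjusted p = 0.129; 0.000152 to 0.439 over 25 alternatives). Of the named probes' values under all alternatives, 2374 stayed on the same side of the threshold, 88 lost and 41 gained a call. A change of direction was counted only for probes called in the main test, and 1 value was reversed. Probes not called there could change sign uncounted, as CHLM did (-0.361, but 0.0278 as deposited). The separate-variance test gave 489 probes higher in root and 607 in leaf. Between the quantile-normalised and deposited intensities 1142 calls were shared, 0 with opposite sign, and with median centring 1183, 2 with opposite sign. With a replicate block, 596 probes were higher in root and 648 in leaf, with 0 gene lists. Same-numbered arrays had deviations correlated at 0.0901 to 0.126, over 0.1 in 2 of 4 pairs, so the numbers were not taken to pair the arrays, although all 8 arrays correlated best with their own number, a hint from the data. Centring on housekeeping genes was not run, since 0 of them had a probe, nor were list tests with missing values or the separate-variance test. Background signal was not used here, so values near 0 set the limit: 1352 of 3439 probes were listed at 0 on at least 1 array.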

Other observations

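All tests of array positions were chosen after the result was seen, and the genes described here were chosen after their values were seen.

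Several further genes, most of them plastid ones, differed between the tissues. AT1G76450, which encodes a PsbP-like protein of the thylakoid lumen, read 2.54 ± 0.278 in leaf and 22.2 ± 4.34 in root (SD, n = 4; log2 difference 3.40 ± 0.24; limma, adjusted p = 3.20e-05), and NdhS (AT4G23890) read 4.41 ± 0.253 and 19.9 ± 1.29 (2.57 ± 0.15, or 1.34 with median centring; adjusted p = 1.02e-05). HEMA3 (AT2G31250), a glutamyl-tRNA reductase of tetrapyrrole synthesis, was higher in root by 1.76 ± 0.19 (0.97 with median centring; limma, adjusted p = 2.67e-04), as was Cpn60beta4 (AT1G26230), a plastid chaperonin subunit listed at 0 on 3 leaf arrays (limma, adjusted p = 0.0121; separate-variance test, 0.0775), and its relative Cpn60beta3, by 0.93 ± 0.22 (1.64 as deposited; limma, adjusted p = 0.0113). CYN (AT3G23490), the cyanase gene, rose from 0.489 ± 0.0833 in leaf to 3.93 ± 0.126 in root (limma, adjusted p = 3.13e-05). PIFI (AT3G15840), which acts in chlororespiration, read 0.375 in leaf and 0.164 in root, a difference of -1.99 after normalisation but -1.20 as deposited (limma, adjusted p = 3.51e-04).

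PRA1.B3 (AT5G05380) was higher in root by 3.58 ± 0.32 and PRA1.B6 (AT5G07110) lower by a difference of -3.12 ± 0.39, both members of a family of membrane trafficking proteins (limma, adjusted p = 1.02e-04 and 5.27e-04). Among regulators, LAS (AT1G55580), which acts in axillary meristem formation, and IAA31 (AT3G17600), an Aux/IAA protein, were lower in root, at -1.61 ± 0.17 and -1.80 ± 0.26 (limma, adjusted p = 2.21e-04 and 9.52e-04). TCP15 (AT1G69690), a transcription factor, was higher in root by 0.92 ± 0.20 (limma, adjusted p = 8.35e-03), but did not pass after median centring (0.39). All of these kept their sign under the other scalings tried, and IAA31, TCP15 and Cpn60beta3 lost their calls when replicates were averaged within subsets (limma, adjusted p = 0.0513, 0.154 and 0.162).

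Probes whose number was divisible by 6 were silent far more often than the rest. Of 261 such probes, 68.6% were listed at 0 on 6 or more arrays, against 5.8% of the 3178 others, and the highest of 10000 random sets of 261 probes reached 17.6%, which argues against weak genes falling there by chance. That every such spot was blank is argued against by 14 probes that read above the median of each array of a tissue, all numbered from 2316 to 2814. Between numbers 2305 and 2879 only 9 of 48 were silent, against 80 of 98 below and 90 of 115 above, and just below that range, where no number divisible by 6 is present, 18 of 23 probes 1 number lower were silent. Blank or failed spots at the silent positions may be the reason, but 79 of the silent probes carry a gene annotation and no second measurement is at hand, so for these this cannot be told apart from genes that are off; LrgB is among them, and no biological explanation was tested.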
